A study of Mus musculus with 173 samples.

How the data were processed

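Total RNA was taken from the kidneys of 173 F2 males of an MRL/MpJ by SM/J intercross, converted to biotin-labelled sense-strand cDNA and hybridised to Affymetrix arrays, per the labels' protocols. Each kidney was measured on 1 array, and the numbers in the sample titles name separate mice, so each animal was 1 replicate of a single group. The deposited values are on a log2 scale, as the authors made them with the affy package and RMA (background correction, quantile normalization and summary of probes), per the submitters' processing notes. The version of affy and the definition of the transcript probe sets are not given in the sources used here. The deposited table held 37264 transcripts and 173 arrays with no missing values, and values ran from 4.65 to 14.1. Array means lay between 7.48 and 7.60 and array medians between 7.22 and 7.35, so the quantiles of the arrays were close to equal but not identical, and normalization again was one of the alternatives.

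Quantile normalization gives every array nearly the same distribution and removes any difference in total signal between animals, and RMA compresses differences of weakly expressed transcripts towards the background. A sequence difference between the strains under a probe can change its binding without a change in transcript level. Probe-level values and probe sequences were not used here, so expression and binding were not separated, and "expression" stands for the summarised array value throughout.

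The values of 2858 transcripts were identical on every array to those of an earlier transcript (no tolerance), as happens where transcripts share all of their probes, and each such set was kept once, which left 34406 distinct measurements. The filter fixed for the case that gene names were missing kept transcripts with a mean above the median of all transcript means (7.25). It passed 18632 transcripts, or 17110 distinct ones after 1522 identical ones were left out.

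Arrays were compared before they were used together. The Pearson correlation of an array with the median array over the 17110 measurements was 0.993 in the median and 0.961 at the lowest. After each transcript's mean was subtracted, the highest correlation between 2 arrays among 14878 pairs was 0.620, for mice 29 and 103, so no array appeared to be a second copy of another.

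For each transcript, 5 models were fitted by maximum likelihood over the 173 animals. The continuous models were a Gaussian, a skew-normal and a Student t distribution. The class models were 3 Gaussian classes with free means, a common SD and fixed shares of 1:2:1, and 2 such classes with shares of 1:1. A transcript was called discrete when the better class model had a Bayesian information criterion (BIC) lower by more than 10 than the best continuous model. Animals were not assigned to classes. Free class shares were fitted by the same algorithm and compared with 1:2:1 by a likelihood ratio test with 2 degrees of freedom and Benjamini-Hochberg adjustment over 23 transcripts, and separately over all 76 with outer classes more than 8 SDs apart. Intervals are 95% percentile intervals from 100 bootstrap draws of animals, or from 10000 draws of co-segregating groups where so stated. Co-segregation was measured by the Spearman correlation over animals, and transcripts were linked at an absolute value above 0.5. These thresholds of co-segregation, the free shares and the position of the middle class were chosen after the data had been seen, while the class models, the filter and the BIC threshold were fixed before the data were examined.

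The class models were tested on simulated data with 200 transcripts per setting, with levels drawn from the real transcripts. The SD within classes was drawn evenly between the lower and upper quartiles of the real transcripts' SDs over animals. Simulated 1:2:1 transcripts with the middle class at the log2 midpoint were called in all 200 cases when their outer classes were 8 SDs apart, in 33.5% at 6 SDs and in 4.0% at 5 SDs. With the middle class above the midpoint by 0.2 of the distance to the high class, 70.5% were called at 6 SDs and all 200 at 8 SDs. Simulated 1:1 transcripts were called in 81.5% of cases at 3 SDs and in 1.0% at 2 SDs. Of 17110 simulated Gaussian transcripts 3 were called, and of 2000 skewed and 2000 heavy-tailed ones none was (0 of each). Simulated 1:2:1 transcripts that were called were better described by 1:1 in 1 of 8 cases (12.5%) at 5 SDs, and in 0 of 67 and 0 of 141 cases at 6 SDs for the 2 positions of the middle class. The 5 transcripts of the 1:1 kind had outer classes 4.78 to 6.47 SDs apart under the 1:2:1 model, so these are the settings closest to them.

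Transcripts were to be named as the 15 with the largest SD, the 15 discrete ones with the largest separation and members of gene lists, all with gene symbols. No table used here pairs the Ensembl transcript identifiers with symbols or positions, so only the 2 transcripts with the largest separation were named by that rule, and 2 of the 1:1 kind were added after their values were seen. For the same reason 8 planned results were not run: the spread and the co-variation of gene lists, pairs of list scores, regressions on podocyte, albumin uptake and tubular injury scores, the comparison of X-linked with autosomal transcripts, and the co-variation of neighbouring genes. The check of the animals' sex by sex-linked genes was not run either. The result that was run was repeated with a BIC difference of 20, with the Gaussian as the one continuous model, without the filter, with a filter at the 60th percentile, without the 5 arrays of lowest correlation with the median array over all 37264 transcripts, with the first 5 principal components removed and with arrays quantile-normalized again. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.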

Results

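Kidney transcript levels were measured in 173 male mice of the F2 generation of an intercross between MRL/MpJ females and SM/J males, both of which are inbred strains. The animals were 13 weeks old, had been housed singly for 3 days and had fasted for 4 hours, and the labels state that all were kept under the same conditions. They are described as part of a cross of 371 F2 animals, and the series title places the work in the study of genes and pathways related to the excretion of albumin in urine. Albumin values and genotypes were not used here, so the 173 kidneys formed 1 group, and the comparison the design allowed was the spread between animals that carry different combinations of the 2 parental genomes. The array values were summarised for 37264 Ensembl mouse transcripts, named by transcript identifiers that the files do not pair with gene symbols or chromosome positions. The account is therefore given by transcripts and by groups of transcripts, and 4 identifiers stand as examples.

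Most kidney transcripts differed little between the animals. Among the 17110 distinct transcript measurements above the median level, the median SD over the 173 animals was 0.11 on the log2 scale, and the median span from the 5th to the 95th percentile of animals was 0.34, a 1.27-fold difference. The SD exceeded 0.5 for 81 transcripts and 1 for 10 transcripts. The range over animals was above 3 log2 units (8-fold) for 42 transcripts. The number of arrays limits the precision of these values, and the spread between animals includes the error of a single array, because each kidney was measured once.

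The second question was whether any transcript fell into the discrete expression classes that segregation of parental alleles produces in an F2 cross. An autosomal locus gives 3 genotype classes in the ratio 1:2:1. A locus on the X chromosome gives 2 classes in the ratio 1:1 in males, which receive their single X from an F1 mother. Discrete classes were called for 211 of the 17110 transcripts (1.23%), of which 206 were better described by 3 classes in the ratio 1:2:1 and 5 by 2 classes in the ratio 1:1. Linked at an absolute Spearman correlation above 0.9 over animals, the 211 fell into 148 sets, so counts of transcripts are not counts of separate findings. The transcripts that varied most were often discrete: 12 of the 15 transcripts with the largest SD, 58 of the 100 with the largest SD, and 8 of the 10 with an SD above 1 were among the 211. In simulations of 17110 continuous (Gaussian) transcripts the same procedure made 3 calls, all of the 1:1 kind. Below the median level, where array signal is closer to background, discrete classes were called for 27 of 17296 distinct measurements (0.156%).

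The 1:2:1 transcripts differed between their outer classes by a median of 0.92 log2 units, or 1.89-fold, with 5th and 95th percentiles of 1.39-fold and 5.39-fold. Outer classes lay more than 2-fold apart for 86 of the 206 transcripts and more than 4-fold apart for 20. The SD within classes had a median of 0.11, so that the outer classes were a median of 7.44 within-class SDs apart. Simulated 1:2:1 transcripts with outer classes 6 SDs apart were called in 33.5% of cases with the middle class at the log2 midpoint, and in 70.5% with it placed above the midpoint by 0.2 of the distance to the high class, close to the median position in the data given below. With the middle class at the midpoint, 4.0% were called at 5 SDs and none (0 of 200) at 4 SDs.

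The transcript with the widest separation was ENSMUST00000072818. Its fitted class levels were 7.25, 12.35 and 12.78 (log2), with a within-class SD of 0.18 (n = 173), and its fitted outer classes differed 46.4-fold in array signal. The low class stood at about the median level of all transcripts on the arrays (7.25), near the levels where signal is closer to background, so this fold is not a measured ratio of transcript amounts. The middle and high classes differed by 0.43. No animal had a value that bridged the gap between the low class and the others. When the class shares were left free, the low, middle and high classes held 21.4%, 56.5% and 22.1% of animals, with 95% bootstrap intervals of 15.6 to 26.9%, 48.0 to 63.1% and 18.0 to 32.1%. The second widest separation was that of ENSMUST00000087657, with classes at 6.17, 7.95 and 8.66 and a within-class SD of 0.12. Its low class lay below the median level of all transcripts, where array signal is closer to background, so the 5.61-fold difference between its fitted outer classes likewise describes array signal alone. Its free class shares were 24.3%, 54.8% and 21.0%.

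**Figure D1:**
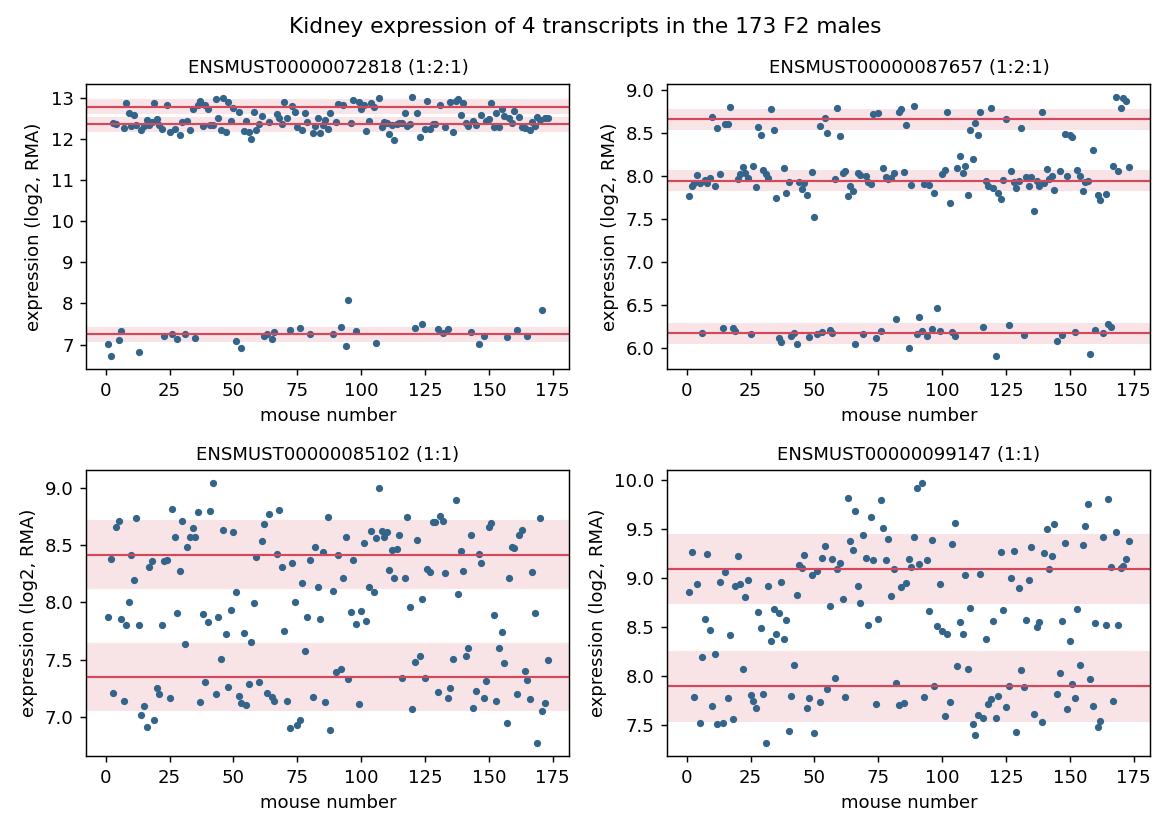
Kidney expression (log2, vertical axis) of 4 transcripts in each of the 173 F2 males (points, by mouse number on the horizontal axis), with the fitted class levels (lines) and 1 within-class SD on either side (bands). ENSMUST00000072818 had classes at 7.25, 12.35 and 12.78 and ENSMUST00000087657 at 6.17, 7.95 and 8.66, while the values of ENSMUST00000085102 and ENSMUST00000099147, fitted by 2 classes, left no empty gap between their classes.

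The calls assumed fixed class shares, and the shares were therefore estimated again without that assumption for the transcripts whose outer classes lay more than 8 SDs apart. These 76 transcripts comprised 2 that co-segregated with no other discrete transcript and members of 21 groups of co-segregating transcripts, described below. Those 2 and 1 transcript from each group made 23. The free shares had medians of 24.3% for the low class, 50.1% for the middle class and 23.9% for the high class. Over the 23 they ranged from 15.6 to 30.1% for the low class, from 42.7 to 59.0% for the middle class and from 18.2 to 31.3% for the high class. Over all 76 the ranges were wider, from 13.9 to 30.1%, from 10.6 to 61.6% and from 16.7 to 69.2%, with the lowest middle share and the highest high share in the same transcript (adjusted p = 0.710 over the 76). These transcripts had been called with shares fixed at 1:2:1, so the closeness of their shares to that ratio is partly set by the selection. None of the 23 sets of shares differed from 1:2:1 after Benjamini-Hochberg adjustment (likelihood ratio test, two-sided, smallest adjusted p = 0.246), and 2 did at an unadjusted p under 0.05, the smallest of which was 0.0107. With all 76 transcripts tested, 1 differed (adjusted p = 0.0020), with free shares of 13.9%, 44.4% and 41.7%, while the transcript with the widest separation in its group had shares of 28.5%, 44.1% and 27.5% (adjusted p = 0.800). With shares left free for all 17110 transcripts, 193 were called, 165 of them also among the 211. Of the 193, 150 were better described by 3 classes and 43 by 2, against 206 and 5 with fixed shares. The 150 transcripts with 3 classes, selected without a fixed ratio, had median shares of 24.3%, 51.2% and 24.2%, with 10th to 90th percentiles of 20.2 to 29.2%, 43.5 to 57.2% and 18.6 to 30.7%. In 26 of the 43 transcripts with 2 classes the smaller class held under 10% of animals.

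**Figure D2:**
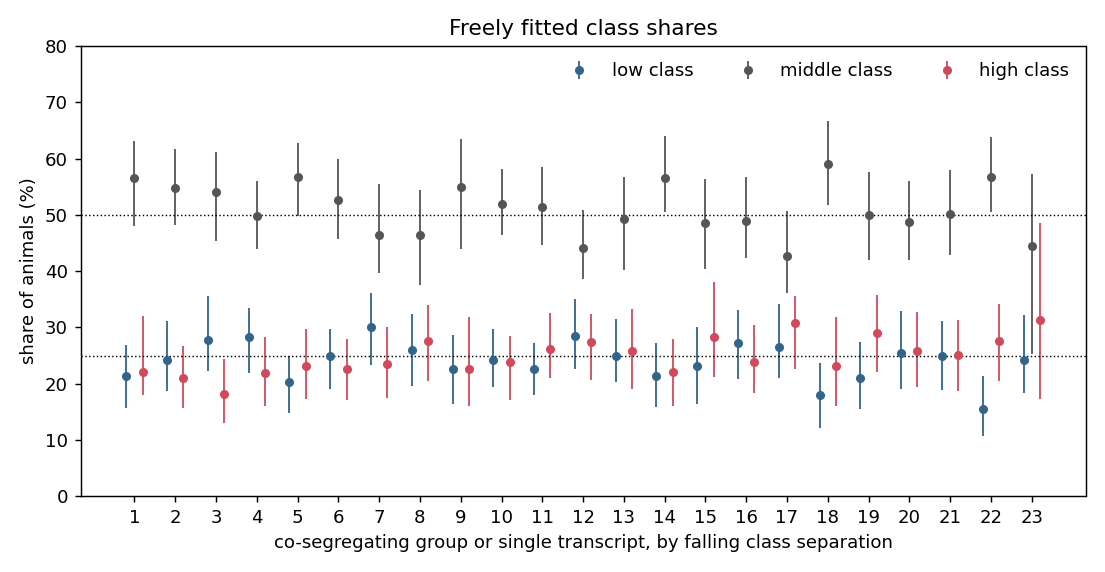
Freely fitted share of animals (%, vertical axis) in the low, middle and high expression class, for 23 transcripts, of which 21 each stand for a co-segregating group and 2 are single (horizontal axis, by falling class separation). Points are estimates over 173 animals, bars are 95% bootstrap intervals over animals, and dotted lines mark 25% and 50%; the middle class held 42.7 to 59.0% of animals in these 23 and 10.6 to 61.6% in all 76 transcripts with outer classes more than 8 SDs apart.

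The middle class did not lie halfway between the outer classes on the log2 scale. It lay above the log2 midpoint for 198 of the 206 transcripts and below it for 8, of which 7 belonged to 1 set of transcripts linked above a correlation of 0.9. On a scale where the low class is at -1, the log2 midpoint at 0 and the high class at 1, the median position was 0.186 (95% bootstrap interval over animals 0.179 to 0.206). All 76 transcripts with outer classes more than 8 SDs apart had the middle class above the midpoint. The middle class lay close to the mean of the outer classes taken on the linear scale, with a median distance of 0.014 log2 units above it (95% bootstrap interval 0.010 to 0.019), against 0.079 above the log2 midpoint (0.072 to 0.086). It was nearer to the linear than to the log2 midpoint for 193 of the 206 transcripts. For small differences the linear and log2 midpoints nearly coincide. Among the 66 transcripts with outer classes 2-fold to 4-fold apart the median distance was 0.015 from the linear midpoint (95% bootstrap interval 0.0030 to 0.022) against 0.15 from the log2 midpoint. Among the 20 more than 4-fold apart it was 0.055 from the linear midpoint (0.032 to 0.110) against 0.61 from the log2 midpoint, and ENSMUST00000072818 lay 0.54 above its linear midpoint.

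**Figure D3:**
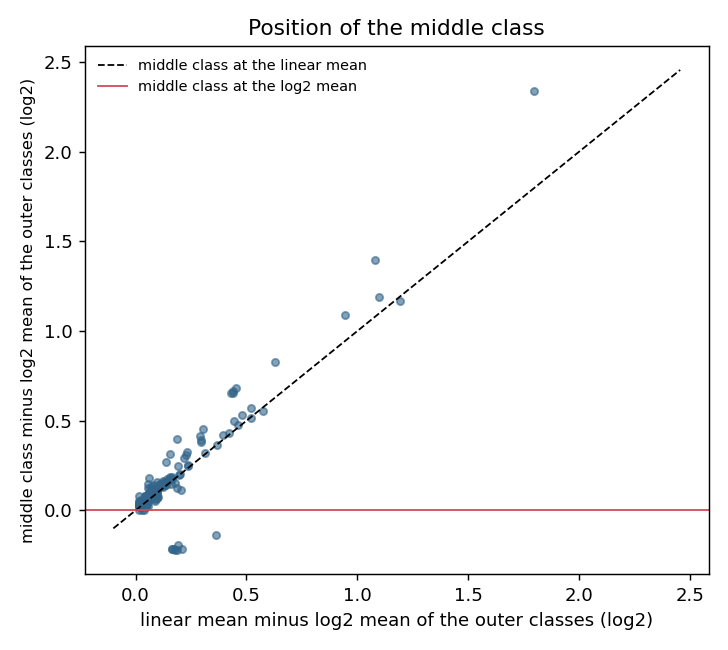
Fitted middle class of the 206 transcripts with 1:2:1 classes, as its distance from the log2 midpoint of the outer classes (vertical axis, log2), against the distance of the linear mean of the outer classes from the same midpoint (horizontal axis, log2). Each point is a transcript; 198 lie above the zero line, and the median distance from the dashed line, on which the middle class equals the linear mean, was 0.014.

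Discrete transcripts varied together in separate groups. Of the 22155 pairs of the 211 transcripts, 751 (3.39%) had an absolute Spearman correlation above 0.5 over the 173 animals, while the median over all pairs was 0.066. When the animals were shuffled independently for each transcript, no pair passed 0.5 in 100 shuffles, and the highest absolute correlation in any shuffle was 0.398. Linking the pairs above 0.5 put 208 of the 211 transcripts into 30 groups of at least 2, of which 17 had at least 5 members, and left 3 transcripts alone. The 3 largest groups had 23, 20 and 17 members. Groups were joined through chains of linked pairs, so members of a group need not all correlate with each other. For the group of 17, the mean z-score of the members, with signs aligned, was not better described by classes (BIC lead over continuous models -1.69). For 1 group of 9 that lead was 1.77, and these were the lowest leads of all groups. Linking gave 16 groups above 0.3 and 43 groups above 0.7. The number of linked pairs was 397 when linked above 0.7, 402 with a BIC difference of 20 and 450 with the first 5 principal components removed. Correlations of both signs occurred within groups: 56.8% of the 641 pairs with an absolute correlation of 0.5 to 0.9 were positive (95% bootstrap interval over groups 51.0 to 65.3%). All 110 pairs above 0.9 were positive. Transcripts of 1 gene share probes on such arrays, and with 1 transcript kept from each set linked above 0.9, 301 pairs above 0.5 remained, of which 56.1% were positive.

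**Figure D4:**
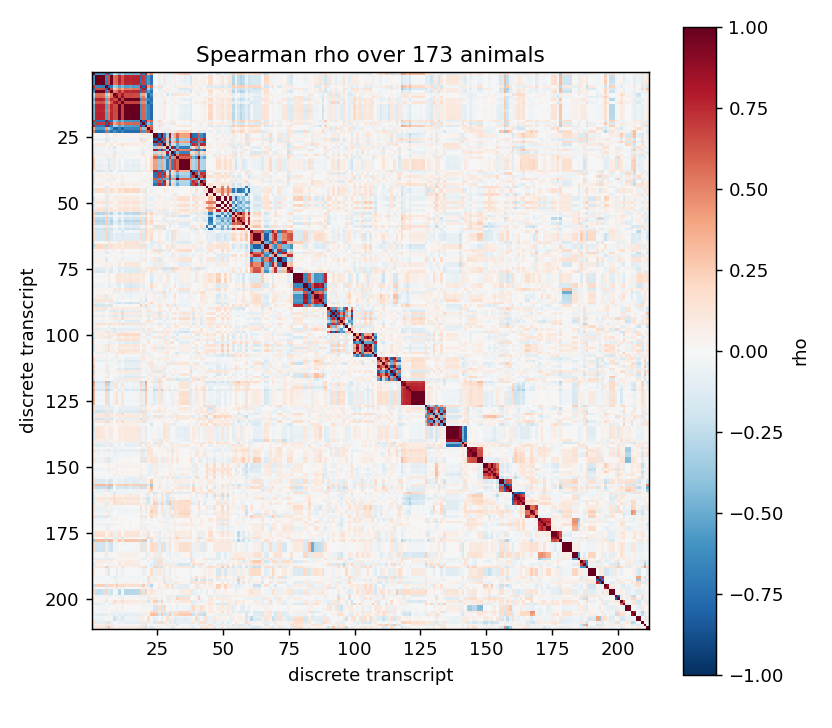
Spearman correlation (colour) over 173 animals between all pairs of the 211 transcripts with discrete classes, numbered along both axes and ordered by co-segregating group, largest group first. Blocks on the diagonal are the groups, the 3 largest of which have 23, 20 and 17 members, and hold positive (red) and negative (blue) correlations.

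Among the 5 transcripts better described by 2 classes in the ratio 1:1, ENSMUST00000085102 had classes at 7.35 and 8.42 with a within-class SD of 0.30, a 2.09-fold difference, and ENSMUST00000099147 had classes at 7.90 and 9.09 with a within-class SD of 0.36, a 2.29-fold difference. Of the 5, these 2 had the largest BIC differences from continuous models (30.8 and 29.9), and they were chosen after their values were seen. The low class of ENSMUST00000085102 stood close to the median level of all transcripts on the arrays (7.25), so its 2.09-fold difference describes array signal alone. In a fit of 2 classes with free shares the low class held 42.9% of animals for ENSMUST00000085102 and 40.3% for ENSMUST00000099147. The better of the free-share fits with 2 or 3 classes led the 1:1 model by a BIC difference of 10.8 and 5.74, respectively. For the first this exceeds the difference of 10 used for calls, so 2 equal classes were not its best description. For the rest of the 5 that lead lay between -2.89 and 1.28. The 1:1 model led the 1:2:1 model by a BIC difference of 12.3 for ENSMUST00000085102, the largest lead of the 5, and of 0.286 for ENSMUST00000099147, the smallest, and by over 6 for 3 of the 5 transcripts. The differences by which the 5 calls led continuous models were above the highest of the 17110 simulated continuous transcripts (15.0) for 3 of the 5. Those simulated transcripts gave 3 calls, all of the 1:1 kind, so the count of 5 alone does not set these transcripts apart from false calls. The count itself depended on the settings: it was 2 with a BIC difference of 20, 3 when counted where the class models differed by a BIC over 6, 9 without the filter and 11 when the first 5 principal components were removed.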

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

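The number of transcripts with discrete classes, 211 in the main setting, lay between 151 and 250 under all alternatives tried, within 1.5 times the main count. Of the 211, 132 were called again after the first 5 principal components were removed, which gave 172 calls, and 203 after arrays were quantile-normalized again. The share of transcripts with the middle class above the log2 midpoint stayed between 91.4 and 99.4%, and its median distance from the linear midpoint between 0.014 and 0.018. The number of transcripts better described by 1:1, 5 in the main setting, was 2 with a BIC difference of 20, 9 without the filter, 11 with the first 5 principal components removed and 3 when counted where the 2 class models differed by a BIC over 6. The number of co-segregating pairs, 751 in the main setting, was 402 with a BIC difference of 20, 450 with the first 5 principal components removed and 397 with pairs linked above 0.7. Fewer transcripts enter with a BIC difference of 20 and with the components removed (172 calls), and fewer pairs can pass above 0.7. How much of the fall in pairs comes from this was not tested, nor was the cause of the other changes. Linking above 0.3 gave 16 groups in place of 30, and linking above 0.7 gave 43. In all, 65 of 73 alternative values stayed within 1.5 times the main value for counts, variance shares and the autocorrelation, within 10 percentage points for the share of middle classes, and within 1 SD over transcripts for their position. The last margin is wide, since the distance from the linear midpoint had 5th and 95th percentiles of -0.035 and 0.143 over transcripts, so it could hardly be missed. Without the 5 arrays, and with arrays quantile-normalized again, the component that matched the second of the main setting came first. Variance shares compared by rank there belong to different components. Linking thresholds, the count with identical transcripts included and the alternatives for groups, middle class and principal components were added after the data had been seen. The 8 results that need gene names, and their other settings, were not run. Arrays give no depth; below the median level, where signal is close to background, 27 further transcripts were called.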

Other observations

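The tests of the linear sum of alleles (over all transcripts and over those more than 4-fold apart), of levelling off among transcripts with a high class above 11, of the X chromosome for the transcript outside its group and of the principal components were chosen only after the result was seen.

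Principal components of the 17110 transcripts showed variation shared by many transcripts. The first component held 11.7% and the second 9.65% of the variance, against at most 1.97% for a first component when each transcript's animals were shuffled. Of the first component, 30.5% came from 4 animals, mice 103, 29, 50 and 47, which, together with mouse 123, were also the 5 arrays with the lowest correlation to the median array over all 37264 transcripts. The second component had a lag-1 autocorrelation of 0.272 along mouse number (permutation test with 10000 shuffled orders, two-sided, p = 0.00060, adjusted p = 0.0060 over 10 components). The other 9 components had values between -0.046 and 0.084, with adjusted p of 0.862 each. The matching component kept a value of 0.253 without the 5 arrays and 0.235 after arrays were quantile-normalized again. The labels give no collection date or array batch.

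The first pattern examined was the middle class, which lay above the log2 midpoint for 198 of 206 transcripts. A bias of the fit is argued against, because middle classes simulated at the midpoint, with outer classes 8 SDs apart, were fitted at a median position of 0.0033 against 0.186 in the data. A levelling off of array signal at high intensity predicts a distance above the linear mean that rises with the level of the high class. The Spearman correlation across transcripts was 0.098 (permutation p = 0.158, 95% bootstrap interval -0.0078 to 0.179), below the 0.3 that was set as its least value. The stricter bound set beforehand for arguing against levelling off was met only narrowly. The value argues against levelling off as a cause across the whole range of levels. Of the 206 transcripts 187 had a high class of at most 11, so the correlation says little about levelling off at the highest levels. For the 19 transcripts with a high class above 11 levelling off stays open: 17 of them lay above the linear mean, by a median of 0.057 (95% bootstrap interval 0.032 to 0.066) against 0.014 (0.0086 to 0.018) for the other 187, but among the 19 the correlation with the level was 0.321 with a permutation p of 0.182 (bootstrap interval 0.147 to 0.563). A sum of the 2 alleles on the linear scale stays undecided. The median distance of 0.014 above the linear mean over all transcripts was small, but its interval (0.010 to 0.019) excludes 0, as do those for the transcripts 2-fold to 4-fold apart (0.0030 to 0.022) and more than 4-fold apart (median 0.055, 0.032 to 0.110). The margin of 0.05 beyond which the sum would have been rejected was set after the data had been seen, and for transcripts up to 2-fold apart it is wider than the median gap of 0.043 between the linear and log2 midpoints, so it cannot tell the 2 midpoints apart there. Such a sum does not account for the 7 transcripts of 1 near-identical set below the log2 midpoint (the eighth below it had undecided classes). Nor does it account for the 0.54 by which ENSMUST00000072818 exceeded its linear midpoint. Binding differences at probes, and where they would place the middle class, were not tested.

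The second pattern was the 30 groups of co-segregating transcripts. Chance correlation among 173 animals gave 0 pairs above 0.5 in 100 shuffles against 751. The prediction set for probes or genes shared by the transcripts of a group was that nearly all pairs are positive. Of the pairs with an absolute correlation of 0.5 to 0.9 only 56.8% were, with both signs in 14 of the 25 groups that held such pairs. Shared probes therefore do not account for the negative pairs, while for groups with 1 sign the signs decide nothing. Transcripts of 1 gene need not vary in the same direction, so the signs cannot decide on shared genes. The 110 pairs above 0.9, all positive, may come from shared probes. Loci that lie close together on a chromosome, or 1 locus that acts on several genes, are candidate explanations that stay open, since positions were not used here. No biological explanation was tested for this pattern.

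The third pattern was the 5 transcripts better described by 2 classes in the ratio 1:1, 4 of which lay in 1 group. The X chromosome of males would make such transcripts co-segregate where they lie close together, and their median absolute correlation was 0.685, above all 10000 random sets of 5 discrete transcripts (95th percentile 0.113, p = 0.0001, the smallest these draws can give), but any cause shared by the 4 predicts the same. For ENSMUST00000099147 the X chromosome is argued against, because an X-linked and an autosomal locus assort independently, while its highest absolute correlation with a 1:2:1 transcript whose outer classes lay over 8 SDs apart was 0.624, against at most 0.398 in the shuffles; the other 4 had 0.203 to 0.298 there, and 0.731 to 0.822 with the fifth member of their group, for which 1:2:1 led 1:1 by a BIC of only 0.171. The mean z-score of that group led the best continuous model by a BIC of 25.2 but favoured 1:1 over 1:2:1 by 4.88. This is less than the 6 needed, so an autosomal locus and an X-linked one cannot be told apart by it. Free shares led both fixed ratios by 15.3 for the fifth member and by 10.8 for ENSMUST00000085102, so neither ratio described these 2 transcripts best. That lead was 5.01 for the mean z-score and between -2.89 and 1.28 for the rest of the group. A shared state that is not genetic stays open, untested. Unequal shares of a 1:2:1 split by chance stay open as well. Of 216 simulated 1:2:1 transcripts called at 5 and 6 SDs, 0.463% were better described by 1:1 (95% binomial interval 0.012 to 2.55%), against 5 of the 39 discrete transcripts of that separation (12.8%, 4.30 to 27.4%). Counted in this way the bound set beforehand was met, but it took the transcripts as independent, and 4 of the 5 lie in 1 group. The range of separation that defined the 39 was also taken from the 5 themselves, so it holds all 5 by construction. Only 8 of the 216 were called at 5 SDs, and 1 of these 8 (12.5%) was better described by 1:1, so the pooled share mostly reflects 6 SDs. Counted by groups, which was chosen after the result was seen, 2 of 16 held such a transcript (12.5%, 1.55 to 38.3%). The simulated share lay below this interval too, although the 2 intervals overlap. A share of groups and a share of single transcripts are unlike measures, so the count by groups cannot decide. Batches that follow the order of the animals are argued against by a median lag-1 autocorrelation of 0.020, with an upper 95% bound of 0.137 from the spread of shuffled orders, below the 0.3 that was set as its limit.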
